A study of Zea mays with 2 samples.

How the data were processed

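RNA-seq had been done on endosperm of maize (Zea mays) kernels collected 15 days after pollination, from the defective kernel mutant dek44 and from wild type. The labels list 1 library per genotype, while the series text speaks of triplicate profiling; 1 column of values per genotype was used here, and whether it pools several plants or libraries is not given in the sources used here. Per the labels' protocols, total RNA was extracted with Trizol, cleaned and treated with DNase I on a column kit, and libraries were made with standard Illumina protocols.

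The deposited values are RPKM, reads scaled to gene length and library size, for 41406 gene models in each library. Reads had been aligned with Bowtie 0.12.2 to the maize build B73 RefGen_v3, per the submitters' processing notes. The counting rule, the treatment of reads that match several places, the use of strand and the gene lengths are not given in the sources used here. Values of near-identical gene copies, the zein families above all, are therefore uncertain gene by gene, and so are those of overlapping and antisense genes. RPKM is relative to the library: when a few abundant transcripts take fewer reads, the values of all other genes go up.

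Depth was recovered from the RPKM values, since each is a whole number of reads divided by gene length and library total. The recovered totals were 22612657 reads for the dek44 library and 20861135 reads for wild type. With them, the values of 39505 of the 39505 genes above 0 in at least one library came out as whole reads, within 0.001 reads plus a relative 1e-06, for some gene length of 100 or more bases. RPKM fixes the totals only up to a factor shared by both libraries. Had a factor of 2 been lost, nearly all recovered gene lengths would be even; 43.6% of 491 were, so none was restored, and larger shared factors were not tested. The read numbers of each gene are the smallest that fit, so true reads may be a multiple of them. Tested on simulated data of the 41406 genes, the procedure gave back 2 of 3 pairs of totals before the test for a factor of 2 and 3 of 3 after it, and the reads of 98.2% of 2795 genes were whole divisors of the true ones.

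Ratios are log2((dek44 RPKM + 1)/(wild-type RPKM + 1)), which understates the change of low genes. Genes with an RPKM of at least 1 in at least one library were called expressed, and those with a ratio of at least 2-fold on that scale were counted. With 1 column of values per genotype there is no replicate check. No p-value is given, and each value describes these libraries, not the genotypes. Plain fold ratios carry a 95% exact conditional binomial (Clopper-Pearson) interval from the smallest recovered reads. These intervals cover counting error only and are wide where true reads are a multiple. For a gene with 0 reads in one library, the fold is given against a floor of 3 reads in that library. That floor leaves out the counting error of the other library, so the lower end of the interval, which can be lower, is given beside it. In simulated libraries of the 41406 genes with no difference, counting error alone took 120 genes past 2-fold higher and 96 past 2-fold lower among 29154 expressed genes. Of 200 simulated genes changed 4-fold, all placed at a mean RPKM of at least 5, 100% passed the 2-fold threshold. Genes of lower RPKM were not tested in this way, and there the added 1 can hide such a change.

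Gene names came from the RefSeq gene table of assembly Zm-B73-REFERENCE-NAM-5.0, matched through gene identifiers among its synonyms. It is another build than that of the files, so no coordinates are given and it served only for names and for which genes neighbour each other. Of the 41406 identifiers, 16689 (40.3%) matched, and 2296 (5.55%) had a name beyond a locus, clone or marker number. The table holds no gene descriptions. The 26 gene lists fixed before the data were examined were written as patterns for descriptions and symbols, and only the symbol patterns could be used. As a result 4 lists had no member (mitochondrial ribosomal proteins, nuclear-encoded respiratory complexes, cytosolic and plastid ribosomal proteins) and 3 had only 1 or 2 expressed members (histones, alternative respiration, embryo-surrounding region markers). For the other 19, the median ratio over expressed members was compared with 10000 random lists of the same size, matched on mean log2(RPKM + 1) in 20 bins, and the percentile is given as a description. Of 200 random lists from the simulated unchanged libraries, 2.5% fell outside the central 95% of their random lists. Those lists were random draws with counting error only. The figure thus checks the calculation and says nothing about lists whose members vary together.

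The genes named were chosen by a rule fixed before the data were examined: the 12 highest and 12 lowest ratios among genes with an RPKM of at least 5 and a reference description, up to 4 members of each list by size of ratio and 2 by mean RPKM, and a set of endosperm and alternative oxidase genes by symbol. As the table has no descriptions, a reference name was required in their place, a reading made after the data were seen. The rule's own fallback for that case, at most 2 identifiers in each direction, is also reported. Genes named outside the rule are said to be so where they appear. The gene that carries the dek44 mutation is not named in the labels or the name table, so its level was not analysed here, and neither was aox3.

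Alternatives were pseudocounts of 0.1 and 5, no filter and a filter at RPKM 5, a 4-fold threshold, and rescaling to a median ratio of 0, to the sum outside the zein list or by a trimmed mean (30% trimmed at each end). After the data were seen, wider name patterns, lists without 13 misfitting homonyms, recovered reads without a pseudocount, and rescaling to the sum outside the 100 most abundant genes were added, as were 7 further gene lists. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.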

Results

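Transcript levels were measured in maize endosperm, the storage tissue of the kernel, 15 days after pollination. The comparison was between a library of the defective kernel mutant dek44 and a library of wild type, 1 of each, and it asked which transcripts differ in the mutant endosperm. The recovered depth was 22612657 reads for dek44 and 20861135 reads for wild type. No replicate values were available for either genotype, so no difference below has a replicate check or a test, and intervals cover counting error only. Across 30136 expressed genes, log2(RPKM + 1) of the libraries correlated with Pearson's r = 0.871 and Spearman's rho = 0.846; genes are not independent replicates.

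In the dek44 library 28 of 29 zeins and 8 of 19 genes of starch synthesis were at least 2-fold lower, while an alternative oxidase gene, 18 of 20 glutathione S-transferases, 13 of 16 cell cycle genes and 10 of 10 markers of the basal transfer layer were at least 2-fold higher. Of the 30136 expressed genes, 9529 were at least 2-fold higher and 1116 at least 2-fold lower on the log2(RPKM + 1) scale. The 95% counting interval of the fold excluded 1 for 9262 of the higher genes and 1077 of the lower ones. The median log2 ratio of all expressed genes was 0.62, so the split depends on the scaling. Of the genes past 2-fold, 89.5% were higher with the RPKM as deposited, against 54.4% (3609 higher, 3029 lower) with the median ratio set to 0 and 55% (3655 higher, 2987 lower) with a trimmed mean. For many lists the median or the counts are therefore also given relative to the median of all genes.

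**Figure D1:**
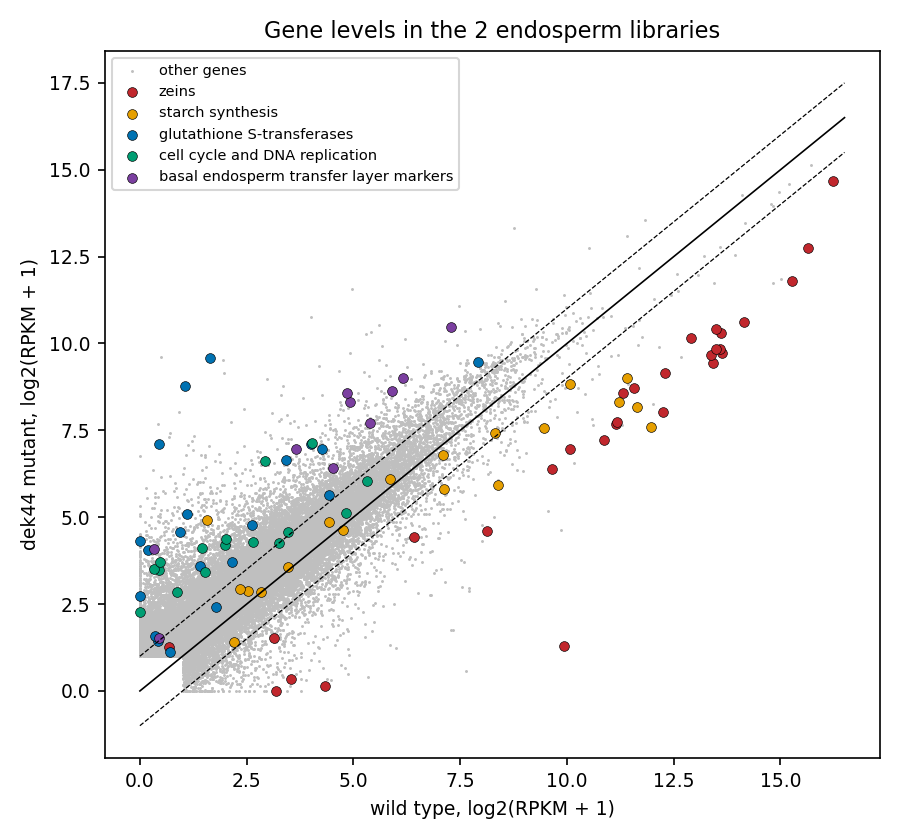
Each point is 1 of 30136 expressed genes, with log2(RPKM + 1) in wild type on the horizontal axis and in dek44 on the vertical axis; the solid line marks equal values, the dashed lines 2-fold, and colours mark members of 5 lists. Of the 29 zeins 28 lie below the lower dashed line, and the 10 expressed transfer layer markers lie above the upper one.

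Zeins, the prolamin storage proteins of maize endosperm, were lower as a group. Of 29 expressed members 28 were at least 2-fold lower and 0 at least 2-fold higher, with a median log2 ratio of -3.33. That is a difference of -3.95 from the median of all genes and below each of 10000 random lists of matched expression. The matching is loose for the most abundant genes, as the highest bin also holds far less abundant ones. The 106 genes with a mean RPKM of at least 1000, zeins among them, had a median log2 ratio of -0.61. For the 1550 genes from 100 to 1000 it was 0.79. Together the 29 zeins, found by name, made up 21.7% of summed RPKM in wild type and 3.68% in dek44. Any zein gene without a matching name is missing from both shares. The most abundant, gz27 (GRMZM2G138727, a gamma zein), had an RPKM of 77278 in wild type and 26132 in dek44, 2.96-fold lower (95% interval 2.93 to 2.98). The gamma zein gz50 (GRMZM2G138689) was 18.9-fold lower (18.3 to 19.6), zp15 (GRMZM2G086294, a beta zein) 7.37-fold lower (7.30 to 7.44) and the alpha zein gene floury2 (GRMZM2G397687) 6.70-fold lower (6.59 to 6.80). The lowest ratio of any gene with an RPKM of at least 5 was that of the alpha zein z1C1_12 (GRMZM2G088365), at 976 in wild type and 1.44 in dek44. Its neighbour z1C1_11 was at 19.3 and 0.0955. Zein copies are near-identical, so reads may have been split or shared between them, and single members are less certain than the family sum.

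Genes of starch synthesis had a median log2 ratio of -0.78 over 19 expressed members, a difference of -1.41 from all genes and below each of the 10000 random lists. Of these, 8 were at least 2-fold lower, 1 at least 2-fold higher and 10 within 2-fold. With the median of all genes set to 0, 11 were lower and 1 higher. For the most abundant members the random lists are only loosely matched, as for the zeins. The ADP-glucose pyrophosphorylase subunit genes bt2 (GRMZM2G068506) and sh2 (GRMZM2G429899), which make the glucose donor for starch, were 20.8-fold (19.98 to 21.8) and 5.29-fold (5.20 to 5.38) lower. The granule-bound starch synthase gene wx1 (GRMZM2G024993) was 11.1-fold lower (10.8 to 11.3), the ADP-glucose transporter gene bt1 (GRMZM2G144081) 7.42-fold lower (7.15 to 7.71) and the branching enzyme gene ae1 (GRMZM2G032628) 2.37-fold lower (2.32 to 2.42). The member that was higher, GRMZM2G039942, shares the name ae1 and had 29.5 in dek44 and 1.95 in wild type. It and an acyltransferase gene in the list (GRMZM2G037104) may not belong to starch synthesis, and without them the median was -0.89 over 17 members.

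Genes of sucrose cleavage and sugar transport went both ways. The sucrose synthase gene sh1 (GRMZM2G089713) was 8.34-fold lower (8.17 to 8.51), whereas the sucrose synthase gene sus1 (GRMZM2G152908) was 3.82-fold higher (3.66 to 3.99) and the cell wall invertase genes mn1 (GRMZM2G119689) and incw1 (GRMZM2G139300) 3.86-fold (3.58 to 4.17) and 11.7-fold (8.07 to 17.6) higher. Over 9 expressed members the median was 1.75, at percentile 99.9 of the random lists, with 5 at least 2-fold higher and 1 lower. With a pseudocount of 5 the percentile was 93.6, and with a filter at RPKM 5 it was 96.7, both inside the central 95% of random lists.

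Among endosperm transcription factors, o2 (GRMZM2G015534), the bZIP activator of zein genes, was 5.66-fold lower (5.42 to 5.91), at 456 in wild type and 80.7 in dek44. Nkd1 (GRMZM2G129261) and fl3 (GRMZM2G006585) were 2.11-fold and 2.06-fold lower. The prolamin-box factor name pbf1 belonged to a pair of identifiers, with log2 ratios of -0.98 and 0.26. The median over 10 members was -0.06, a difference of -0.68 from all genes, at percentile 0.97. Of these, 3 were at least 2-fold lower and 1, vp1, at least 2-fold higher; with the median of all genes set to 0, 5 were lower and 0 higher, vp1 being at 0.93.

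**Figure D2:**
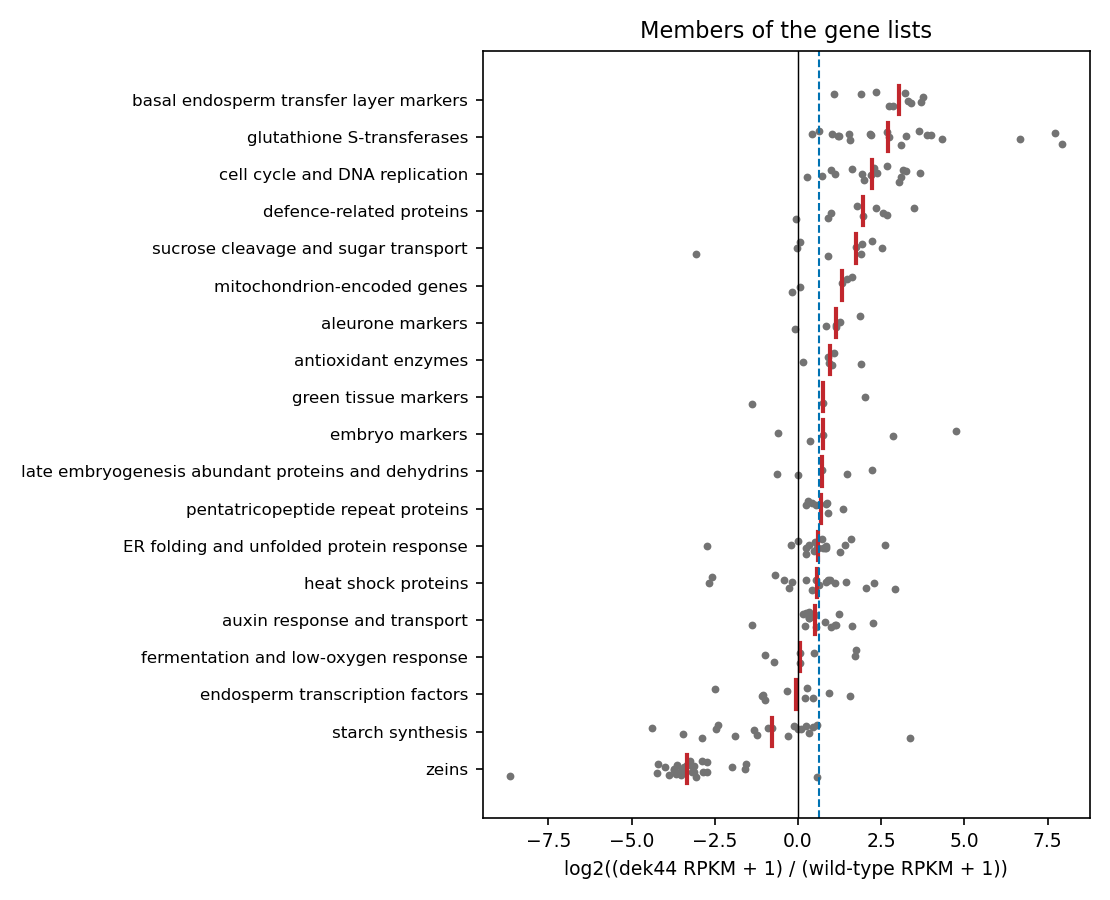
Each grey point is the log2((dek44 RPKM + 1)/(wild-type RPKM + 1)) of 1 expressed member, the red bars are list medians, the solid line marks 0 and the dashed blue line the median of all expressed genes, 0.62. Zeins (median -3.33) and starch synthesis (-0.78) lie at the low end, transfer layer markers (3.03) and glutathione S-transferases (2.71) at the high end.

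Alternative oxidase, which passes electrons from ubiquinol to oxygen without the cytochrome pathway, was far higher. The gene named aox1 and aox2 (GRMZM2G125669) had an RPKM of 261 in dek44 and 0.873 in wild type, 299-fold higher (157 to 654). The other expressed member of the alternative respiration list, the uncoupling protein gene PUMP, was 1.38-fold higher, which is lower than the median of all genes. Of 5 genes that carry names of mitochondrion-encoded subunits, 3 were at least 2-fold higher and 0 lower, with a median of 1.32 at percentile 94.96, but with the median of all genes set to 0 none was past 2-fold (0 higher, 0 lower, median 0.56); nad2 had log2 ratios of 1.47 and 1.63 under its pair of identifiers and nad1 -0.17. Whether those reads came from the mitochondrial genome or from nuclear copies was not resolved. Pentatricopeptide repeat proteins, many of which process organelle RNA, had a median of 0.69 over 8 members, at percentile 60.4. Of these, emp2 has hsbp1 among its other names and may not belong. Without that homonym the median was 0.53 over 7 members, at percentile 41.2. SMK2, the 1 member at least 2-fold higher (log2 ratio 1.37), was listed by its symbol alone and may not belong either.

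Glutathione S-transferases, which conjugate glutathione to reactive compounds, were higher as a group. Of 20 expressed members 18 were at least 2-fold higher and 0 lower (13 and 0 with the median of all genes set to 0), with a median of 2.71, 2.09 above all genes and at percentile 100. The highest ratios were those of gst42 (GRMZM2G025190), at 769 in dek44 and 2.15 in wild type or 358-fold higher (254 to 524), gst2 (GRMZM2G132093), at 438 and 1.07 or 408-fold higher (174 to 1257), and gst41 (GRMZM2G097989), at 137 and 0.364. gst20 (GRMZM2G056388) had 18.98 in dek44 and 0 reads in wild type, at least 93.2-fold higher against a floor of 3 reads (lower end of the 95% interval 75.3). Antioxidant enzymes had a median of 0.96 over 6 members, at percentile 81.4, with 3 at least 2-fold higher, among them sod9 (3.70-fold) and the manganese superoxide dismutase gene sod3 (2.02-fold); with the median of all genes set to 0, 1 was, sod9, and sod3 had a log2 ratio of 0.25.

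Cell cycle and DNA replication genes were higher as a group. Of 16 expressed members 13 were at least 2-fold higher and 0 lower (11 and 0 with the median of all genes set to 0), with a median of 2.24, 1.61 above all genes and at percentile 100. The replication clamp genes pcna1 (GRMZM2G030523) and pcna2 (GRMZM2G108712) were 14.5-fold (11.03 to 19.4) and 9.13-fold (8.01 to 10.4) higher, and the cyclin gene cyc3 39.1-fold higher (18.8 to 98.2). The ribonucleotide reductase small subunit gene RNRS2 (GRMZM2G155546), outside the lists, was at 51.1 and 0.283. The histone list had 1 expressed member, the linker histone gene his1, with a log2 ratio of 1.77.

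Markers of the basal endosperm transfer layer, the cells that take up nutrients from maternal tissue, were higher in dek44 for 10 of 10 expressed members, by at least 2-fold, and for 9 with the median of all genes set to 0. The median was 3.03, 2.40 above all genes and at percentile 100. The gene named bap2 and betl2 (GRMZM2G152655) had 1430 in dek44 and 154 in wild type, 9.26-fold higher (8.65 to 9.92), betl4 (GRMZM2G073290) was 10.9-fold higher (9.70 to 12.4) and betl3 (GRMZM2G175976) 7.29-fold higher (6.53 to 8.16). This list holds mn1 as well. The embryo-surrounding region markers esr2 (GRMZM2G315601) and esr6 (GRMZM2G048353) were 40.4-fold (23.5 to 76.4) and 8.20-fold (6.02 to 11.4) higher. Aleurone markers had a median of 1.15 over 6 members at percentile 92.6. With the median of all genes set to 0 it was 0.46, with 1 member at least 2-fold higher and 0 lower. Green tissue markers had a median of 0.76 over 3 at percentile 62.4. Embryo markers had a median of 0.74 over 5 at percentile 61.2, with 2 at least 2-fold higher and 0 lower (2 and 1 with the median of all genes set to 0). The abundant embryo oleosin gene ole1 was at 372 in dek44 and 289 in wild type, the oleosin gene ole17 at 59.4 and 89.97, and the globulin gene glb1 at 40.4 and 23.9. The 2 at least 2-fold higher were ocl1 (GRMZM2G026643), 17.4-fold higher (12.1 to 25.9) at 10.7 and 0.617, and GLB1 (GRMZM2G067402), whose other names are those of a haemoglobin, at 28.1 and 0.0832. Without misfitting homonyms the embryo marker median was 0.55 over 4 members, at percentile 43.9.

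**Figure D3:**
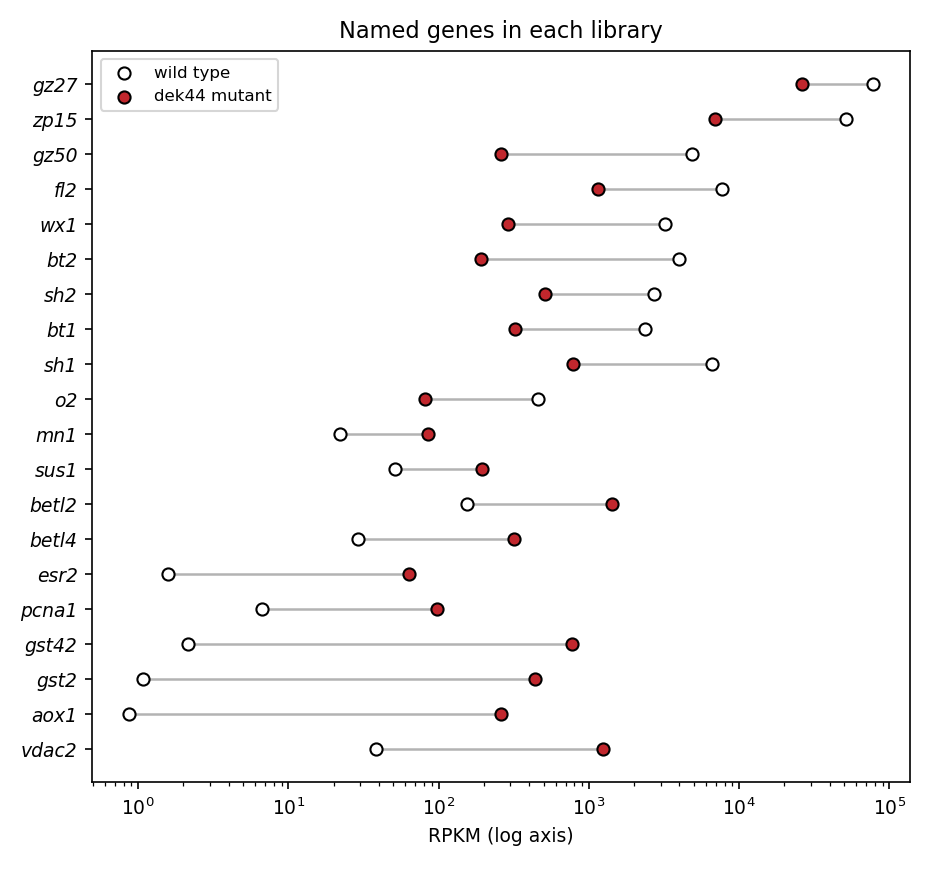
RPKM of 20 genes on a log axis, open circles for the wild-type library and red circles for dek44, joined by a line per gene. From gz27 to o2 the dek44 value is the lower, and from mn1 to vdac2 the higher.

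Defence-related proteins had a median of 1.96 over 9 members, at percentile 99.985, with 6 at least 2-fold higher and 0 lower. PR10 was 7.73-fold higher (5.604 to 10.9), pr5 had 4.91 in dek44 and 0 reads in wild type, at least 3.69-fold higher against that floor (lower end 2.56), and the protease inhibitor gene sci1 was at 1735 and 1827. The list includes pep4 and pep7, names of phosphoenolpyruvate carboxylase. A chitinase gene outside it, chiB (GRMZM2G005633), was 38.9-fold lower (33.1 to 45.95).

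The remaining lists lay within the range of the random lists. Heat shock proteins had a median of 0.58 over 18 members (percentile 45.4), with 5 at least 2-fold higher and 2 lower, or 3 and 4 with the median of all genes set to 0: hsp22 (GRMZM2G007729) was 7.66-fold higher (7.30 to 8.03), at 1073 in dek44, and hsp101 (GRMZM2G360681) 7.28-fold lower (6.55 to 8.12). Endoplasmic reticulum folding genes had a median of 0.59 over 19 members (percentile 51.4). Without misfitting homonyms it was also 0.59, over 15 members (percentile 51.35). The calreticulin gene crt2 was 6.15-fold higher and bip2 3.10-fold higher, while the member that was at least 2-fold lower was the zein floury2. Fermentation and low-oxygen genes had a median of 0.06 over 7 members (percentile 6.78), with adh1 1.65-fold lower and pdc3 3.29-fold higher. The unused description pattern of this list covered haemoglobins. GLB1, which carries haemoglobin names (28.1 in dek44, 0.0832 in wild type), is not among the 7. Auxin genes had a median of 0.51 over 17 members (percentile 33.4). Those values equal those of the name stem arf, so the list describes that stem and not auxin genes at large. In the later scan of name families, the stem aux had a median of 1.23 over 11 members (percentile 97.2). Of these, 6 were at least 2-fold higher and 0 lower. Late embryogenesis abundant proteins had a median of 0.71 over 5 (percentile 53.8), of which a pair named rab2 carries the names of small GTPases. With the median of all genes set to 0, the medians of these 5 lists lay between -0.37 and -0.02, and of the folding genes 1 was higher and 1 lower, of the low-oxygen genes 0 and 2. Without the rab2 pair, the late embryogenesis abundant proteins had a median of 1.46 over 3 members, at percentile 95.54.

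Outside the lists, the higher named genes included the mitochondrial porin gene vdac2 (GRMZM2G115049), at 1236 in dek44 and 37.99 in wild type or 32.5-fold higher (30.1 to 35.2), bap-3a (GRMZM2G133382) at 146 and 1.33, HIT2 at 46.3 and 0.121, LTP3 at 62.5 and 0.777 and the expansin gene expB7 at 33.2 and 0.397. The lower ones included m25 at 0.275 and 19.7 and P4H4 at 12.2 and 191. Taken without regard to names, the highest ratios with an RPKM of at least 5 were those of GRMZM2G079962, at 780 in dek44 and 0.399 in wild type, and gst42, and the lowest those of z1C1_12 and GRMZM2G331701, at 0.496 and 197.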

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

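The alternatives added after the data were seen were the wider name patterns, the lists without homonyms, the reads without a pseudocount and the rescaling to the sum outside the 100 most abundant genes. Counts of genes past the threshold, 9529 higher and 1116 lower as reported, were 4192 and 543 with a pseudocount of 5, which shrinks low genes, and 2084 and 260 at 4-fold. They were 3609 and 3029 with the median ratio set to 0, 3655 and 2987 with the trimmed mean, and 4290 and 2513 with the sum outside the 100 most abundant genes; these scalings move every gene by 1 factor. A pseudocount of 0.1, a filter at RPKM 5 and the sum outside the zeins kept each count within 1.5 times. Taking away the filter cannot change the counts, since with a pseudocount of 1 a gene under RPKM 1 in both libraries cannot reach 2-fold. Leaving the 10 most abundant other genes out of the denominator gave a zein share of 4.19% in dek44 and 27.6% in wild type. The correlation across genes was 0.825 with a pseudocount of 0.1 and 0.909 without a filter. The number of lists outside the central 95% of random lists, 8 as reported, was 7 with the filter at RPKM 5, without sucrose cleavage and sugar transport, and 8 under the 9 others; with a pseudocount of 5 mitochondrion-encoded genes (percentile 98.03) took the place of that list. Of the 113 named genes, 89 moved by more than their counting error (or had no finite interval) with the median ratio set to 0, 68 with the sum outside the zeins and 17 with a pseudocount of 0.1. Of the 88 past 2-fold, 17, 4 and 0 were no longer past it, such as bip2 (0.85), pdc3 (0.95) and atp1 (0.56) with the median ratio set to 0. None of the 88 could change sign, as these scalings move log2 ratios by less than 1 and a pseudocount keeps the sign. No paired analysis was possible because each genotype has 1 column of values, and no test was made. For the same reason limma and leaving out replicates were not run. Depth limits genes near 0 reads, such as the 603 higher genes without a read in wild type.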

Other observations

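The gene lists and name families in the next 2 paragraphs were chosen after the data were seen. Of 17 expressed genes with names of mitochondrial proteins, 13 were at least 2-fold higher in dek44 and 0 lower, with a median log2 ratio of 1.88; with the median of all genes set to 0 there were 9 higher and 0 lower. The list holds aox1 and vdac2, whose ratios were already known when it was made, so it is no independent evidence of a direction. Among the higher ones were the prohibitin gene phb2 (671 in dek44, 53.7 in wild type) and the chaperonin genes CPN60I (491 and 52.6 for GRMZM2G111477) and CPN60II (279 and 36.8). The adenine nucleotide translocator gene ANT-G1 (292 and 271) and the protease gene lon1 (9.03 and 8.59) were near equal. Ribosomal protein genes by name had a median of 1.05 over 38 members, and 0.29 after centring.

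Histones by any name had a median of 1.86 over 12 members and tubulins 2.06 over 13, with 10 and 11 at least 2-fold higher and 0 lower. With the median of all genes set to 0, 9 and 8 were higher and 0 lower. Expansins, which loosen cell walls, had 4 of 8 members at least 2-fold higher, such as expA4 (207 and 10.4), and 2 lower. The medians of glycolytic enzymes and cytokinin response genes were 0.82 and 0.51, each over 13, or 0.05 and -0.08 with the median of all genes set to 0. A scan of 72 families of names with the same stem and at least 6 expressed members put 9 above and 4 below the central 95% of random lists. The 3.6 expected in all holds only if families and their genes are independent. Some stems share members, and the gst and zein stems repeat lists given above, so the scan cannot show an excess over chance. Above were the stems gst, tub, tubb, BURP, Cel (cellulase), GRF, rop, kin and krp, of which tub and tubb, and kin and krp, share members; GRF mixes growth-regulating factor names with a pair of 14-3-3 names. Below, beside the zeins, was the SnRK kinase stem, with a median of -0.75 over 7 members, among them SnRK2.5 (1.74 in dek44, 23.5 in wild type), and the GLK and SBP transcription factor stems (-0.28 and 0.15).

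Of the tests that follow, those on the 100 most abundant genes and on gene length were chosen before their results were seen, and the others after. Many more genes were higher than lower in dek44, 9529 against 1116. When RPKM was rescaled to the sum outside the 29 zeins found by name, the median log2 ratio stayed at 0.43 (bootstrap interval 0.42 to 0.44), but 14 unnamed genes among the 100 most abundant, such as AF546188.1_FG007 (33044 in wild type, 3708 in dek44), were also at least 2-fold lower, so this does not settle how far freed storage protein reads go. The shift was present in each of 4 bins of recovered length, each of 6001 to 6017 genes, with a lowest median of 0.58. Genes with under 50 reads in all were outside the bins. A recovered length is the true one or a fraction of it, so long genes can lie in short bins. A part played by true gene length is therefore not excluded. Rescaling to the sum outside the 100 most abundant genes, which held 55.3% of summed RPKM in wild type and 27.5% in dek44, left 0.11 (0.10 to 0.12), an interval that spans the bound of 0.1 set for this test. This rescaling makes the sum of all other genes equal in both libraries, so it brings their median near 0 whichever genes changed. How much of the shift comes from fewer reads on the 100 genes therefore cannot be told. A change in total RNA per cell was not tested.

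Transfer layer and embryo-surrounding region markers were higher, while 28 of 29 zeins and 8 of 19 starch synthesis genes were at least 2-fold lower. A smaller share of starchy endosperm in the sampled tissue was taken to raise the markers of the other cell types alike. The transfer layer median exceeded the aleurone median by 1.88 (bootstrap interval 1.09 to 2.73, over 10 and 6 genes). Of those 6 aleurone genes 3 (a2, bz1, bz2) are pigment genes, so how well the list marks aleurone is uncertain. With the median of all genes set to 0, the 2 embryo-surrounding region markers had a median of 3.01 and the transfer layer markers 2.26. Both of these types were raised, and an equal rise in every type is only an assumption. The test therefore does not decide, and a smaller share of starchy endosperm stays open. Embryo tissue would raise embryo markers, whose median lay at percentile 61.2, or 43.9 without misfitting homonyms. With the median of all genes set to 0, ole17, ole1 and glb1 had log2 ratios of -1.34, -0.40 and -0.004, against 2.18 for ocl1. Members thus lay far apart, so embryo tissue stays open. An effect of the genotype within the transfer layer, and endosperm that is developmentally younger at the same age, may also apply; neither was tested.

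The zein copies z1C1_11, z1C1_12 and z1C1_13, 3 consecutive entries in the reference order, were almost without signal in dek44. The log2 ratio of z1C1_12, -8.65, lies below the range of the other 26 zeins, -4.24 to 0.58. This copy was singled out for its low ratio, so that comparison cannot decide whether the fall shared by the zeins is the whole account. Its RPKM in dek44 was 0.382% of the median of 9 other z1C copies, so few of their reads were counted on it there. That low value was also why it was singled out, so it excludes no explanation. Neither z1C1_11 nor z1C1_13 can be told apart from the fall shared by the zeins. z1C1_11 was 202-fold lower (counting interval 35.7 to 8006). The lower end lies between the 37.9-fold of z1A1_8, whose smallest recovered number in dek44 is 1 read, and the 18.9-fold of gz50, the next zein. z1C1_13 went from a smallest recovered number of 18 reads to 0. True reads of these copies may be a multiple, which would narrow the intervals. With at most 1.97% of the wild-type signal of z1C1_12, both z1C1_11 and z1C1_13 may hold only reads spilled over from it. A run of 3 near-absent neighbours came up in at most 0.01% of random placements, the smallest share the draws can give, but this decides nothing, as the run prompted the test and can be 1 gene counted 3 times. A deletion or sequence difference at z1C1_12 between the plants sampled stays open, and genomic reads were not analysed here.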
